A study of Mus musculus with 4 samples.

How the data were processed

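RNA from 4 samples of cultured mouse astrocytes, 2 with a control shRNA and 2 with an shRNA against Phf8, was sequenced. Per the labels' protocols, libraries were made from total RNA with a stranded kit after ribosomal RNA depletion and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, the tools named are HISAT2 (an aligner), HTSeq (a read counter) and DESeq2 with the mm10 build, with no versions and no settings. The strand setting of the counting and the annotation release are not given in the sources used here. The deposited files give, for each of 55421 genes with chromosome, start, end and strand, a whole-number count of reads, which was read as a raw count per gene because the totals differ between libraries. Of the gene identifiers, 55154 had a symbol and 267 had none, and the latter held about 0.005% of the reads of a library. GENCODE M21, an annotation of the same build, held 55240 of the identifiers, 54985 of them with the same start and end, and was used for gene types, exonic lengths and overlaps. A symbol shared by more than 1 identifier (213 identifiers had such a symbol) was given to the identifier with the most reads. No gene was left out before the filter, and the deposited coordinates are printed.

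Groups were taken from the sample titles. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts of all 4 libraries, without covariates. Genes were kept by edgeR's filterByExpr, libraries were scaled by TMM (factors 1.02 and 1.01 for the control and 0.967 and 0.997 for the Phf8 shRNA libraries), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold change. The test is two-sided. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. The TMM scaling assumes that most genes do not differ, and here more than 50% were called, so the balance of higher and lower calls depends on the scaling.

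Before the data were examined, a rule for the genes to name and 27 gene lists were fixed. The rule took Phf8, the 12 higher and 12 lower genes with the largest absolute log2 fold change among called genes with a mean of at least 2 CPM and non-overlapping groups (leaving out predicted genes, pseudogenes and small RNA genes), up to 4 called members of each list with the smallest p, and the markers Gfap, Aqp4, Slc1a2, Aldh1l1 and S100b. Some genes that the rule takes are not reported here. The lists covered astrocyte identity, synaptogenic factors, synaptic components, neuron, progenitor, oligodendrocyte, microglia, endothelial and mural, and matrix genes, reactive astrocytes, S and G2/M phase, interferon, NF-kB, p53, the unfolded protein response, immediate early genes, Notch, BMP and TGF-beta, cholesterol, glycolysis, adhesion, channels, histone demethylases and methyltransferases, ribosomal proteins and oxidative phosphorylation. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and also with an estimated correlation and with fry. A member known to the annotation under another symbol was looked up under it. For genes with few reads, the ratio of reads was given with its 95% exact binomial counting interval.

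The fit was tested on simulated counts drawn from the means and library sizes of these libraries, in which 50 genes were changed at each of 4 folds among 20657 genes tested. It recovered 40 genes at 1.25-fold, 47 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, with 10 false calls. The simulated spread was that estimated from these libraries, and few genes were changed, in both directions alike. The simulation therefore tests neither the scaling where 52.1% of genes are called nor whether the spread is biological. Its false calls do not give the error rate of the calls in the data. A raised list was called with the preset correlation and 0 of 26 unchanged lists were, while with an estimated correlation the raised list was not called. The depth behind these values was 36839530 to 44724759 reads per library.

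The alternatives were other scalings (DESeq2's size factors, library size alone and the upper quartile), DESeq2 1.42.0 and limma-voom as tools, a robust fit, other low-count filters, the replicate number as a block, leaving out each library in turn, leaving out mitochondrial and the 20 most abundant genes, and other thresholds. Alternatives chosen after seeing the data were a biological coefficient of variation set to 0.1, 0.2 or 0.4, and the gene lists under upper-quartile scaling and without the mitochondrial and most abundant genes. After seeing the data, 3 further lists (motile cilia, targets of SRF and YAP, and a second list of oligodendrocyte genes) were written without the genes already seen among the top genes, and are reported in the closing observations, the second oligodendrocyte list also beside the first.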

Results

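Messenger and other long RNA was measured by stranded, ribosomal RNA-depleted sequencing in mouse astrocytes that had been obtained in culture by differentiating C57BL/6J neural stem cells in serum-containing medium. The astrocytes had been infected with a lentivirus carrying either a control short hairpin RNA (shRNA) or an shRNA against Phf8. An shRNA is processed in the cell into a small RNA that directs degradation or silencing of its target transcript. Phf8 encodes a histone demethylase of the Jumonji family that removes methyl groups from lysines of histones H3 and H4. The series comprised 2 control shRNA libraries and 2 Phf8 shRNA libraries. Reads assigned to genes amounted to 42245602 and 40472627 in control shRNA replicates 1 and 2, and to 44724759 and 36839530 in Phf8 shRNA replicates 1 and 2. Between 29701 and 30196 of the 55421 listed genes had at least 1 read in a library. Levels below are CPM (the reads of a gene relative to the total of its library) scaled by the trimmed mean of M-values (TMM), given as mean ± SD of n = 2 libraries, and fold changes are those of Phf8 shRNA over control shRNA.

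The libraries of a group were close to each other. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.995 between both control libraries and 0.995 between both Phf8 shRNA libraries, against 0.958 to 0.963 between libraries of different groups. The counts of both libraries of a group still differed by more than sampling noise, with a chi-square per degree of freedom of 3.18 in the control group and 2.88 in the Phf8 shRNA group, and each library was counted as 1 sample, as the labels give them. That excess over sampling noise does not show whether they came from separate cultures. The share of reads from the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 was 21.2% and 22.5% in the control libraries and 27.8% and 28.2% in the Phf8 shRNA libraries. Gm26917, a transcript overlapping ribosomal RNA sequence, took 0.500% and 0.452% of control reads and 0.704% and 0.729% of Phf8 shRNA reads.

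The comparison of Phf8 shRNA with control shRNA asks which transcripts depend on Phf8 in astrocytes. The targeted gene was lower in both Phf8 shRNA libraries. Phf8 (ENSMUSG00000041229), located on the plus strand of chromosome X from 151520672 to 151633859 in the mm10 build, stood at 53.2 ± 0.152 CPM in control and 43.3 ± 1.44 CPM in Phf8 shRNA astrocytes. This was a log2 fold change of -0.30 ± 0.06 (SE), or 18.5% less transcript, with an adjusted p of 1.72e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the genes that passed the test, 78.0% had a larger absolute fold change than Phf8. The protein was not measured in these data.

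Expression differed widely between the groups. Of 21042 genes tested, 10965 (52.1%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5225 of them higher and 5740 lower with Phf8 shRNA. The median absolute log2 fold change of the changed genes was 0.58. A change of at least 2-fold was seen in 2990 genes, of which 1157 rose and 1833 fell, and a change of at least 4-fold in 205 genes that rose and 674 that fell. Of 14109 protein-coding genes tested, 8518 changed. Higher genes made up 47.6% of the calls with TMM scaling, 58.0% with upper-quartile scaling (6640 higher and 4811 lower) and 40.3% with the library size alone. The design text calls the samples biological replicates without saying whether they were separate cultures, animals or infections, so the p-values measure only the spread between these samples, which may be technical. With a common biological coefficient of variation of 3.64%, small differences passed the test. When that coefficient was set to 0.2, a value chosen after seeing the data, 3305 genes changed and Phf8 no longer passed (adjusted p = 0.639, edgeR's likelihood ratio test with Benjamini-Hochberg adjustment).

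**Figure D1:**
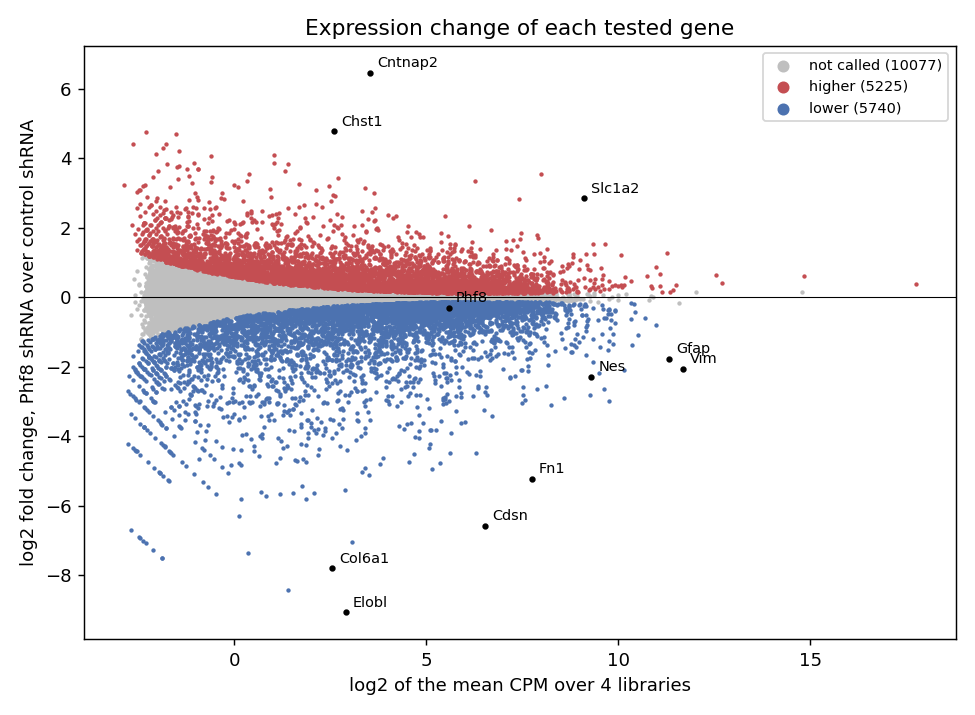
Each point is 1 of the 21042 tested genes, with the log2 of its mean CPM over the 4 libraries on the horizontal axis and the log2 fold change of Phf8 shRNA over control shRNA on the vertical axis. Genes that passed edgeR's quasi-likelihood test are red (5225 higher) or blue (5740 lower), the other 10077 are grey, and the lower genes reach larger fold changes than the higher ones.

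Cntnap2 and Chst1 were among the genes with the largest increases. Cntnap2 (chromosome 6, 45059357 to 47304213), which encodes a neurexin-related adhesion protein, rose from 0.259 ± 0.124 to 23.1 ± 4.99 CPM (log2 fold change 6.46 ± 0.16 SE). Chst1 (chromosome 2, 92599707 to 92615250), which encodes a carbohydrate sulfotransferase, rose 27.4-fold from 0.426 ± 0.0840 to 11.8 ± 0.302 CPM. The top 12 also held Neu4, Abhd3, Gcnt4, Cyp4f15, Enpp6, Slc25a34, Efhd1 and Ppp2r2c, and the log2 fold changes of these and Chst1 ran from 2.94 for Ppp2r2c to 4.78 for Chst1. The largest adjusted p among the top 12 was 1.5e-53 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Exons of Efhd1 and Gcnt4 overlapped a gene on the opposite strand over 11.9% and 10.5% of their length, and their levels are uncertain to that degree because the strand setting of the counting is not given in the sources used here.

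Among the 12 genes with the largest decreases were Fn1, Cdsn and the collagen VI genes Col6a1 and Col6a2. Fn1 (chromosome 1, 71585520 to 71653200), which encodes fibronectin, fell 37.2-fold from 418 ± 11.5 to 11.2 ± 0.455 CPM. Cdsn (chromosome 17, 35552128 to 35557180), which encodes the adhesion protein corneodesmosin, fell from 182 ± 7.10 to 1.89 ± 0.472 CPM (log2 fold change -6.57 ± 0.09 SE). The collagen VI genes Col6a1 and Col6a2, which lie near each other on chromosome 10, fell with log2 fold changes of -7.78 ± 0.26 and -5.62 ± 0.27 (SE). They had 4 and 9 Phf8 shRNA reads, with depth-adjusted ratios of 234 (95% counting interval 91.1 to 860) and 50.4 (26.4 to 111). Col6a3, another collagen VI gene that the fixed rule does not take, rose at a low level. It went from 0.072 ± 0.036 to 0.318 ± 0.090 CPM (log2 fold change 2.09 ± 0.59 SE). Ccn2, which encodes a matrix-associated growth factor, fell from 8.26 ± 0.0406 to 0.163 ± 0.00110 CPM, and 23.2% of its exonic length overlapped a gene on the opposite strand. Cfap52 and Dnah6, genes of the ciliary axoneme, fell with log2 fold changes of -5.53 ± 0.17 and -5.02 ± 0.14 (SE). Mrgprf, Nos1 and Emp1 were also among the 12, at -7.02, -5.81 and -5.10. Mrgprf and Nos1 each had 10 Phf8 shRNA reads, with depth-adjusted ratios of 134 (95% counting interval 72.4 to 279) and 57.4 (31.0 to 120). Elobl had 1260 control and 2 Phf8 shRNA reads, a depth-adjusted ratio of 598 (95% counting interval 165 to 4947), and Pdgfb, a platelet-derived growth factor gene, had 447 and 1 reads, a ratio of 425 (75.8 to 16807). The largest adjusted p among these 12 genes was 7.7e-91 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the intervals cover counting error only.

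Astrocyte identity genes went in both directions. Gfap, the intermediate filament of astrocytes, fell from 3971 ± 152 to 1172 ± 209 CPM (log2 fold change -1.76 ± 0.07 SE), and the water channel gene Aqp4 fell from 1337 ± 20.0 to 532 ± 71.3 CPM (-1.33 ± 0.06 SE). Slc1a2, the main astrocytic glutamate transporter, rose 7.20-fold from 135 ± 0.284 to 975 ± 9.64 CPM. Aldh1l1 and S100b fell by smaller amounts, with log2 fold changes of -0.31 and -0.32, and 11.1% of the exonic length of Aldh1l1 overlapped a gene on the opposite strand. Clu fell 3.64-fold, whereas Mfge8 rose 2.64-fold. Of the 25 identity genes tested, 8 rose and 14 fell (8 and 15 when adjusted over the list alone), and neither camera nor fry called the list (median log2 fold change -0.31, adjusted p = 0.265 and 0.665). Among 30 astrocyte channels and transporters, 13 rose and 13 fell (14 and 13 when adjusted over the list alone), with a median of 0.09, a camera adjusted p of 0.488 and an adjusted p of 0.0134 by fry, directed upward. The cystine transporter gene Slc7a11 rose 3.50-fold and the GABA transporter gene Slc6a11 rose 3.28-fold, while the urea transporter gene Slc14a1 fell 4.42-fold.

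**Figure D2:**
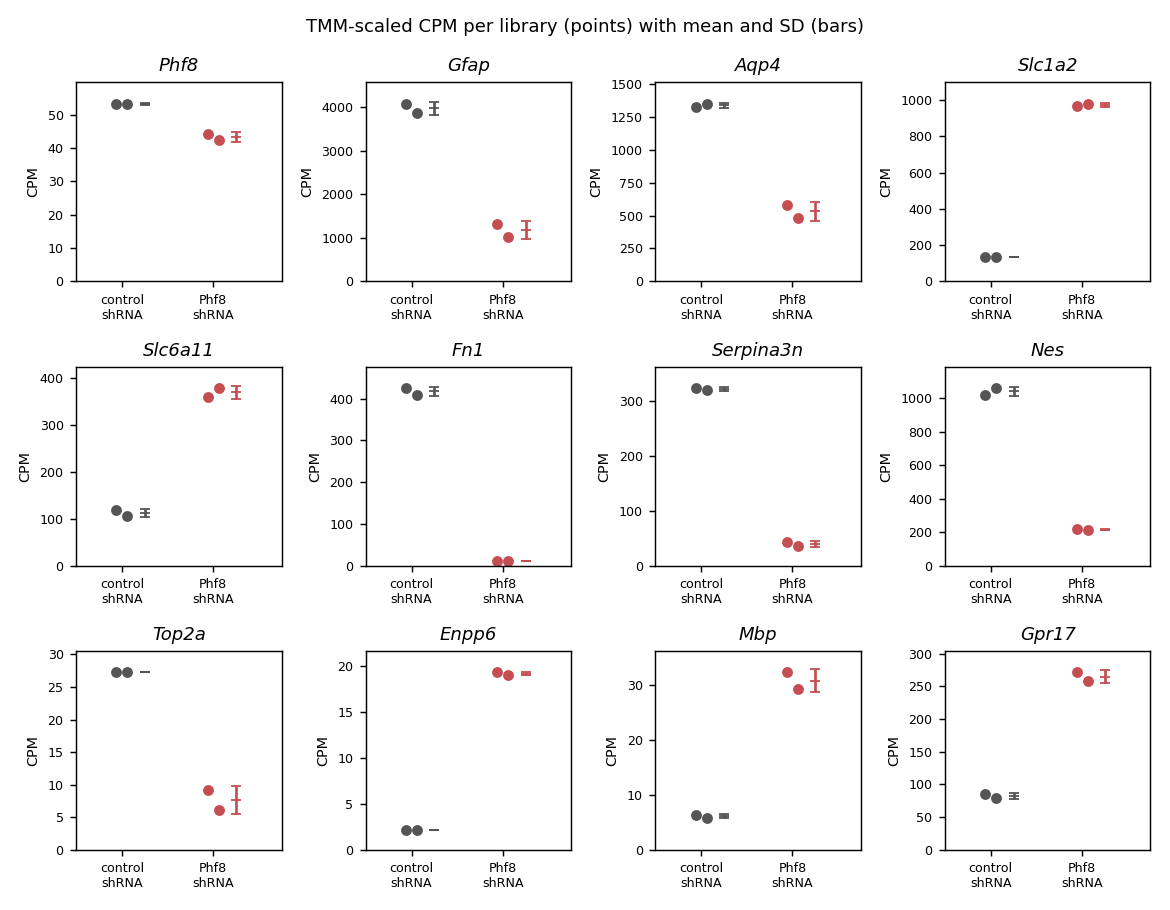
Points give the TMM-scaled CPM of each of the 4 libraries for 12 genes, on a linear axis from 0, and the bars beside them give the mean and SD of the 2 libraries of each group (control shRNA grey, Phf8 shRNA red). Phf8, Gfap, Aqp4, Fn1, Serpina3n, Nes and Top2a lie lower and Slc1a2, Slc6a11, Enpp6, Mbp and Gpr17 lie higher in both Phf8 shRNA libraries than in both control libraries.

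Genes of reactive astrocytes fell together. Cd109 fell 8.47-fold, the protease inhibitor gene Serpina3n 8.18-fold, the sphingosine phosphate receptor gene S1pr3 7.41-fold from 676 ± 21.1 to 91.1 ± 8.63 CPM, and the oncostatin M receptor gene Osmr 7.07-fold. Of 25 tested members, 22 fell, 20 of them at least 2-fold, and 1 rose, with a median log2 fold change of -2.89. The camera adjusted p was 2.0e-10 with the preset correlation, and the call was lost at an adjusted p of 0.34 with an estimated correlation. Camera, which compares a list with the other genes, was run over 27 lists fixed before the data were examined, with a preset correlation of 0.01 between genes. It called 14 of them. With the correlation estimated from these libraries, camera called 0 lists. Its smallest adjusted p was 0.34, and 2 lists had an unadjusted p under 0.05. That form of camera has little power with n = 2 libraries per group, and it also missed the raised list of the simulation. The estimated correlation lay below the preset 0.01 for some lists that lost their call, at -0.067 for neuron markers and 0.0057 for G2/M genes. It lay above 0.01 for others, at 0.25 for reactive astrocyte genes. A call lost in that form therefore does not count against a list. Fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, called 19. For 8 lists the count adjusted over the list alone differed from that over all genes and is given beside it, and for the other 19 lists both counts were equal.

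**Figure D3:**
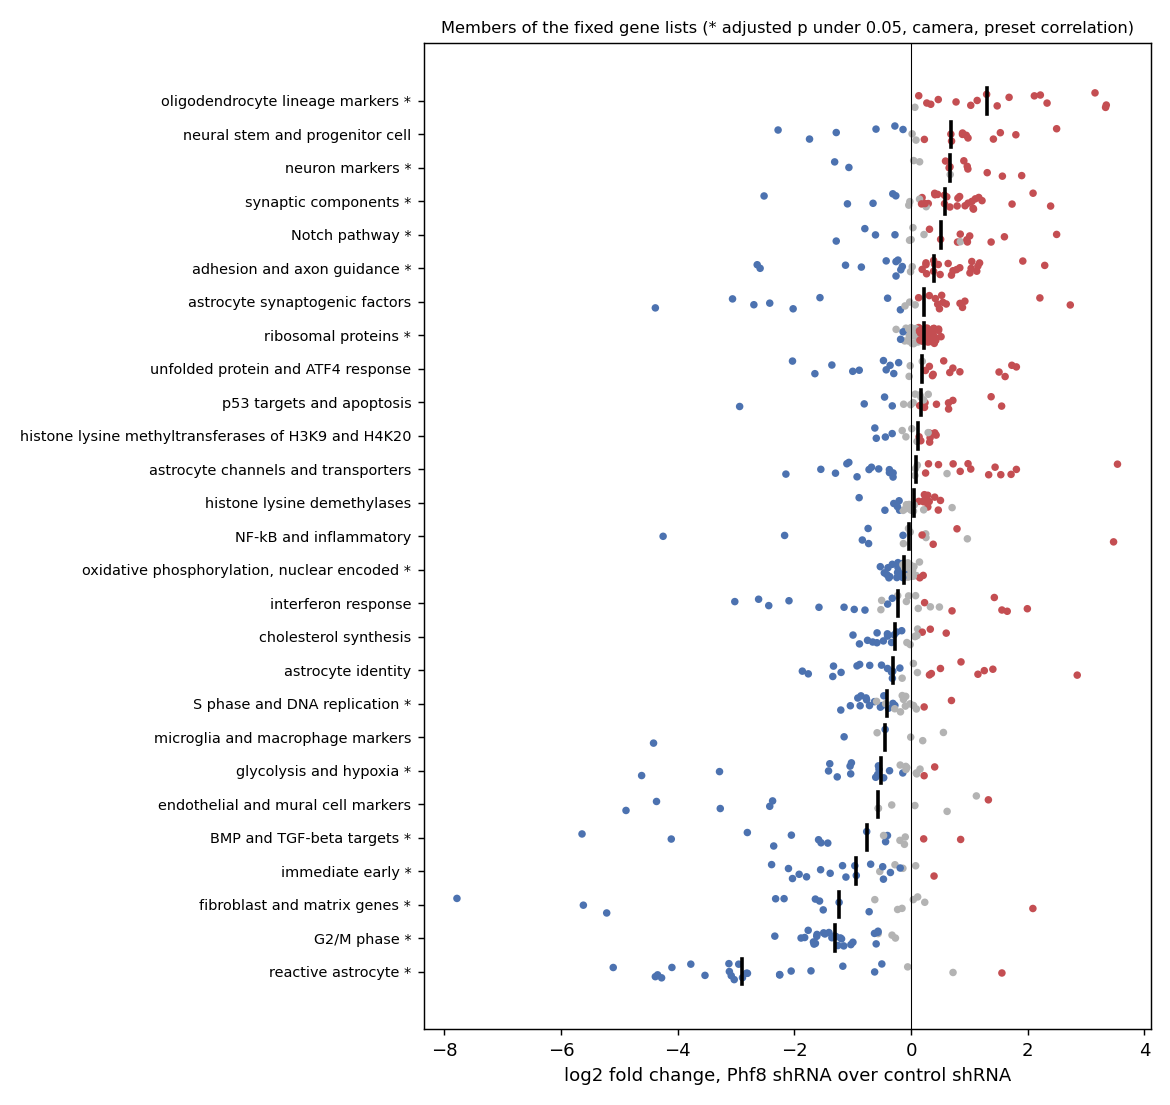
Each point is a tested member of 1 of the 27 gene lists, placed by its log2 fold change of Phf8 shRNA over control shRNA (red, higher and blue, lower past the test, grey, not past it), with a black bar at the list's median and vertical scatter within a list added for legibility. Medians run from -2.89 for reactive astrocyte genes to 1.30 for oligodendrocyte lineage markers, and asterisks mark the 14 lists called by camera with the preset correlation.

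Extracellular matrix genes, genes of BMP and TGF-beta signalling and immediate early genes were also lower. In the fibroblast and matrix list, 17 of 24 genes passed the low-count filter. Of these 17, 10 fell and 1, Col6a3, rose, with Col5a2 down 4.52-fold and Col5a1 down 5.00-fold beside Fn1 and Col6a1 (median -1.23, camera adjusted p = 3.4e-04, adjusted p = 0.34 with an estimated correlation). In the BMP and TGF-beta list, which holds ligand genes such as Bmp6 beside target genes, 11 of 17 fell and 2 rose. Its median was -0.76, with a camera adjusted p of 4.0e-04 and an adjusted p of 0.34 with an estimated correlation. Id3 fell 5.11-fold and Bmp6 fell 6.99-fold there, beside Ccn2, whereas Id2 rose 1.80-fold. Immediate early genes, which respond within minutes to stimulation, included 16 that fell and 1 that rose among 21 (17 and 1 when adjusted over the list alone). Their median was -0.94 and their camera adjusted p 2.0e-05, and the adjusted p was 0.46 with an estimated correlation. Fosl2 fell 5.24-fold, Atf3 4.09-fold, Fos 2.17-fold and Ier3 4.29-fold.

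The list of astrocyte synaptogenic factors, which holds secreted factors, membrane adhesion proteins and phagocytic receptors, had members that fell and members that rose. The thrombospondin genes Thbs1 and Thbs2 fell 8.34-fold (29.4 ± 1.66 to 3.51 ± 0.338 CPM) and 5.36-fold, Sparc, whose product is known to oppose synapse formation, fell 2.95-fold and Chrdl1 fell 6.47-fold. Over the whole list of 24 tested genes, 13 rose and 8 fell. The genes that rose, named after their values were seen, were the membrane adhesion genes Nlgn1, Nlgn2, Nlgn3, Nrcam and Pcdhgc5, the ephrin gene Efnb2, the phagocytic receptor genes Megf10 and Mertk, and Gpc5, Wnt3, Wnt7a, Sparcl1 and Tnc. The median log2 fold change was 0.22 and the mean -0.24, camera gave an upward direction that did not pass (adjusted p = 0.488), and fry gave a downward direction that passed (adjusted p = 0.00258).

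Synaptic, neuronal and axon guidance genes were mostly higher. Among synaptic components, 25 of 34 rose and 5 fell (median 0.57, camera adjusted p = 5.0e-05, adjusted p = 0.34 with an estimated correlation). The glutamate receptor genes Grin2b and Gria1 rose 3.32-fold and 4.27-fold, the synaptotagmin gene Syt1 rose 2.32-fold and the neurexin gene Nrxn2 rose 2.10-fold. Among 20 neuron markers, 14 passed the low-count filter, of which 9 rose and 2 fell (median 0.67, camera adjusted p = 0.00101, adjusted p = 0.34 with an estimated correlation). Gad1, a GABA-synthesising enzyme gene, rose from 41.6 ± 0.557 to 103 ± 2.81 CPM, Dcx, a gene of migrating neurons, rose from 111 ± 7.21 to 208 ± 2.24 CPM, and Celf4 and Elavl3 rose 2.96-fold and 1.95-fold. Of 34 adhesion and axon guidance genes, 22 rose and 10 fell (median 0.39, camera adjusted p = 0.0100, adjusted p = 0.34 with an estimated correlation). Sema5a and Dcc rose 4.90-fold and 2.21-fold, while Nrp2 and Cdh4 fell 6.01-fold and 2.18-fold. The fixed list of oligodendrocyte lineage markers, another glial type, moved up with these lists at a median of 1.30.

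In the fixed list of oligodendrocyte lineage markers, most members rose. The myelin basic protein gene Mbp rose 5.04-fold from 6.12 ± 0.363 to 30.8 ± 2.15 CPM, Gpr17, a marker of cells about to mature, rose 3.21-fold from 82.5 ± 4.87 to 265 ± 9.74 CPM, and Enpp6 rose 8.90-fold. Of 17 tested markers, 16 rose, 11 of them at least 2-fold, and 0 fell (median 1.30, camera adjusted p = 1.3e-07, adjusted p = 0.34 with an estimated correlation). In a split not fixed beforehand, the progenitor-stage markers Olig1, Olig2, Pdgfra and Cspg4 had a median of 0.30 (0.066 to 0.467). The other 13 markers had a median of 1.68 (0.132 to 3.35). In the control libraries 14 of the 17 had a mean of at least 1 CPM. In a second oligodendrocyte list, chosen after the data were seen, 12 of 27 tested genes rose, 7 fell and 8 did not pass (median 0.05, camera adjusted p = 0.59). The lists of microglial and of endothelial and mural markers had medians below 0. Of 18 microglia and macrophage markers, 7 passed the low-count filter. Of these 7, 0 rose and 3 fell (median -0.44, camera adjusted p = 0.304, fry downward with an adjusted p of 0.00828), and 3 had a control mean of at least 1 CPM. Cd68 fell 2.22-fold, and Adgre1 had 50 control and 2 Phf8 shRNA reads, a ratio of 23.7 (95% counting interval 6.2 to 202). Of 16 endothelial and mural markers, 12 passed the filter. Of these 12, 1 rose and 5 fell (median -0.56, camera adjusted p = 0.130, fry downward with an adjusted p of 0.0141), and 6 had a control mean of at least 1 CPM. Camera called that list without Phf8 shRNA replicate 2 (median -1.19, adjusted p = 0.0427) and with no low-count filter (0.0496). Acta2, Kdr and Kcnj8 fell 20.6-fold, 9.64-fold and 29.6-fold, the last from 132 to 4 reads, and Pdgfrb rose 2.51-fold.

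Genes of neural stem and progenitor cells changed in both directions, and genes of the cell cycle were lower. Nes, the intermediate filament of neural progenitors, fell 4.85-fold from 1042 ± 28.6 to 215 ± 2.73 CPM and Prom1 fell 3.34-fold, whereas the fatty acid binding protein gene Fabp7 rose from 419 ± 3.78 to 1209 ± 101 CPM and the Notch effector Hes5 rose 5.64-fold. Of 19 tested progenitor genes, 11 rose and 6 fell (median 0.68, camera adjusted p = 0.0585, fry upward with an adjusted p of 0.00804). Camera called the list with the library size alone (adjusted p = 0.0362), with no low-count filter (0.0168), without control shRNA replicate 1 (0.0347) or 2 (0.0467) and without Phf8 shRNA replicate 2 (0.0488), but not with the upper quartile (0.0943) or without the mitochondrial and most abundant genes (median 0.46, 0.109), and the adjusted p was 0.42 with an estimated correlation. In the Notch pathway list, 10 of 19 rose and 4 fell (median 0.51, camera adjusted p = 0.0241, adjusted p = 0.42 with an estimated correlation). Notch3 and Dll1 rose 2.59-fold and 1.95-fold and Lfng fell 1.73-fold. Opposite-strand genes overlapped 31.8% of the exonic length of Hes5 and 20.6% of that of Dll1. Genes of G2 and M phase fell in 25 of 28 cases and rose in 0 (27 and 0 when adjusted over the list alone), with a median of -1.30 and a camera adjusted p of 3.6e-10, and an adjusted p of 0.34 with an estimated correlation. Top2a fell from 27.3 ± 0.0185 to 7.62 ± 2.15 CPM, Mki67 fell 3.06-fold, Kif11 fell 2.48-fold and Cenpe fell 2.56-fold. In S phase and DNA replication, 15 of 28 genes fell and 2 rose, with Mcm6, Mcm4, Mcm5 and Uhrf1 down 1.70-fold, 1.71-fold, 2.30-fold and 1.81-fold (median -0.41, camera adjusted p = 0.00149, adjusted p = 0.51 with an estimated correlation).

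Members of the inflammatory and stress lists changed in both directions, and camera called none of these lists. In the interferon response list, 6 of 25 genes rose and 10 fell (median -0.23, camera adjusted p = 0.247, fry downward with an adjusted p of 0.0141), with Ifi27, Ifit2 and Ifih1 down 2.98-fold, 1.96-fold and 5.42-fold and Ifit3b up 3.99-fold. Among NF-kB and inflammatory genes, 4 of 16 rose and 6 fell (5 and 6 when adjusted over the list alone), with a median of -0.03 that became 0.05 under upper-quartile scaling, a camera adjusted p of 0.853 and an adjusted p of 0.0231 by fry, directed downward. Traf1 fell from 6.96 ± 0.292 to 0.360 ± 0.0469 CPM, Csf1 fell 1.67-fold and Nfkb1 1.66-fold, and Cxcl5 rose from 0.108 ± 0.0547 to 1.23 ± 0.230 CPM. Of 21 p53 targets and apoptosis genes, 9 rose and 4 fell (9 and 5 when adjusted over the list alone), with a median of 0.17, a camera adjusted p of 0.169 and a fry adjusted p of 0.250. The death receptor gene Fas fell 7.67-fold, while the cell cycle inhibitor gene Cdkn1a, Sesn2 and Btg2 rose 2.59-fold, 1.64-fold and 1.56-fold. Of 25 genes of the unfolded protein and ATF4 response, 12 rose and 10 fell (median 0.19, camera adjusted p = 0.488, fry adjusted p = 0.115). The chaperone gene Hspa5 fell 3.13-fold, while the amino acid transporter gene Slc7a5 and the lipoprotein receptor gene Vldlr rose 3.06-fold and 2.84-fold.

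Genes of glycolysis and hypoxia were lower. Ndrg1 fell 24.6-fold, Pfkp, a phosphofructokinase gene, fell 9.73-fold from 99.6 ± 1.71 to 10.2 ± 0.465 CPM, and Ldha and the glucose transporter gene Slc2a1 fell 2.03-fold and 2.06-fold. Of 24 tested members, 15 fell and 2 rose (median -0.51, camera adjusted p = 0.00101, adjusted p = 0.53 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 22 cases and rose in 3, with Sqle, Fdft1 and Nsdhl down 1.99-fold, 1.84-fold and 1.58-fold, but neither camera nor fry called the list (median -0.27, adjusted p = 0.0585 and 0.0847), and 11 fell and 7 rose with upper-quartile scaling. Camera called it with the library size alone (14 fell and 2 rose, adjusted p = 0.0386), with no low-count filter (0.0202), without control shRNA replicate 2 (0.0467) and without Phf8 shRNA replicate 1 (0.0124), and the adjusted p was 0.75 with an estimated correlation. Fdft1 was overlapped on the opposite strand over 18.3% of its exonic length.

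Most ribosomal protein genes rose by less than 2-fold, and 18 of 40 nuclear genes of oxidative phosphorylation fell. Rps15, Rps21, Rpl13 and Rpl31 rose 1.43-fold, 1.34-fold, 1.34-fold and 1.34-fold, and 51 of 74 ribosomal protein genes rose while 2 fell (52 and 2 when adjusted over the list alone). Their median was 0.21 and ranged from 0.16 with the library size alone to 0.30 with upper-quartile scaling. Camera gave an adjusted p of 4.4e-05, and the adjusted p was 0.68 with an estimated correlation and 0.102 by fry. Levels of ribosomal protein genes are uncertain because near-identical processed pseudogenes can share their reads, and 25.3% of the exonic length of Rpl31 was overlapped on the opposite strand. Ndufa4, Ndufb10, Ndufa9 and Uqcrb fell 1.44-fold, 1.37-fold, 1.30-fold and 1.32-fold, and 2 oxidative phosphorylation genes rose while 20 did not pass. With the library size alone 28 fell and 0 rose, and with upper-quartile scaling 11 fell and 6 rose. Their median was -0.12 with a camera adjusted p of 0.0432 (-0.17 and 0.0101 with the library size alone), and the adjusted p was 0.75 with an estimated correlation. That call was also lost without control shRNA replicate 1 (median -0.11, adjusted p = 0.169), without Phf8 shRNA replicate 2 (median -0.05, adjusted p = 0.338), with a minimum mean of 1 CPM (0.0821), with upper-quartile scaling (median -0.04, adjusted p = 0.160) and by fry (0.190). In these ribosomal RNA-depleted libraries, reads of ribosomal RNA rose together, mt-Rnr1 with a log2 fold change of 0.63 ± 0.09, mt-Rnr2 with 0.38 ± 0.11 and Gm26917, which overlaps nuclear-encoded ribosomal RNA, with 0.64 ± 0.07 (SE). The share of reads from mitochondrial protein-coding genes was higher too, at 1.41% and 1.42% in the control and 1.77% and 1.86% in the Phf8 shRNA libraries.

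Other histone lysine demethylase genes changed by less than 2-fold. Phf2 rose 1.32-fold and Kdm7a fell 1.36-fold, both close relatives of Phf8, and Kdm6b and Kdm4b rose 1.42-fold and 1.38-fold. Of 26 demethylase genes tested, Phf8 included, 10 rose and 6 fell (10 and 7 when adjusted over the list alone). With the library size alone 9 of these genes rose and 9 fell, and with upper-quartile scaling 13 rose and 5 fell. Their median of 0.05 turned to -0.00440 with the library size alone, and the camera adjusted p was 0.439. Among 16 genes for methyltransferases and readers of the marks on histones H3 and H4, 7 rose and 4 fell (median 0.12, camera adjusted p = 0.488). The heterochromatin protein genes Cbx5 and Cbx1 fell 1.54-fold and 1.36-fold, and Prdm16 and Kmt5b rose 1.35-fold and 1.25-fold. Among the genes named in these comparisons by the fixed rule, the largest adjusted p was the 1.72e-06 of Phf8 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.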

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

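The alternatives that set the biological coefficient of variation, and the gene lists under upper-quartile scaling or without the mitochondrial and most abundant genes, were chosen after seeing the data; the others were fixed beforehand. Besides Phf8, the 126 genes that the fixed rule takes kept their direction and their call in all 1760 values computed under the settings fixed beforehand. Most of them were picked for a large fold change or a small p in these same libraries, so this stability was largely fixed in advance. They were not computed with a set coefficient of variation. The number of changed genes (10965) stayed within 1.5 times under other scalings, filters and tools, from 7512 with DESeq2 to 11451 with the upper quartile, and was 12044 at an adjusted p under 0.1. Leaving out each library in turn gave 9053 to 10235, where the spread came from the group that kept both libraries and the lone library was assumed to vary like them, so these fits, also among the 1760, do not test the spread of the other group. DESeq2 called 3170 genes higher and 4342 lower. Requiring at least 2-fold left 2990 genes, 1157 higher and 1833 lower, because fewer genes meet it. With a coefficient of variation of 0.1, 7210 genes changed (3317 higher), with 0.2, 3305 (1262 higher, 2043 lower), and with 0.4, 811 (172 higher, 639 lower). Phf8 stayed near a log2 fold change of -0.30 in these fits and its call was lost, with adjusted p of 0.110, 0.639 and 1 from edgeR's likelihood ratio test. Its fold change ranged from -0.35 to -0.21 under the other settings, all past the threshold.

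No pairing by replicate number was seen: deviations of same-numbered libraries correlated at -0.00102 across genes. Libraries of a group were so close that an effect of a shared culture could be too small to show. The value therefore cannot tell whether same-numbered samples were paired. With the replicate block 10929 genes changed (5202 higher, 5727 lower), Phf8 was at -0.30 and 14 lists were called, and the block changed no call of a list or named gene.

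Of 27 lists, 14 were called, and 13 to 17 under the other camera settings with the preset correlation, 0 with an estimated correlation and 19 by fry. The 0 does not count against a list, because that form of camera also missed the simulated raised list. The synaptogenic list (median 0.22) was directed upward by camera and downward by fry; the cause was not tested. The median of the NF-kB list ran from -0.17 to 0.088 when each library was left out, and the direction of camera turned without Phf8 shRNA replicate 2 (median 0.03); the cause was not tested. Depth limits mainly genes with few reads, such as Pdgfb with 1 read in the Phf8 shRNA libraries.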

Other observations

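The lists of motile cilia genes, of targets of the transcription factors SRF and YAP and of further oligodendrocyte genes were written, and all tests on them chosen, after the genes with the largest changes had been seen, and they leave those genes out; the members named as examples were also chosen after their values were seen. The test on the share of changes of at least 2-fold and that on the other cell type lists were chosen after the result was seen.

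Genes of motile cilia, the beating cell projections of ependymal and airway cells, were lower. Foxj1, the master transcription factor of motile ciliogenesis, fell from 139 ± 6.20 to 29.0 ± 0.756 CPM (n = 2 libraries each), a log2 fold change of -2.27 ± 0.06 (SE), and the dynein gene Dnah5 fell 6.42-fold and the radial spoke gene Rsph1 fell 7.62-fold. Of 64 tested members, 55 fell (48 at least 2-fold) and 2 rose, with a median of -1.88. The camera adjusted p over the 3 added lists was 1.9e-18 with the preset correlation, and the adjusted p was 0.042 with an estimated correlation. Targets of SRF and YAP, which respond to actin tension, were also lower. Ccn1 fell 8.89-fold, Myl9 fell 7.95-fold, and Flna fell 2.71-fold from 1079 ± 44.2 to 398 ± 5.67 CPM. Of 42 tested members 33 fell and 5 rose (34 and 5 when adjusted over the list alone), with a median of -0.84, a camera adjusted p of 6.7e-10 and an adjusted p of 0.29 with an estimated correlation.

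Single values outside the lists also stood out, chosen after they were seen. The imprinted transcript H19 fell 10.4-fold from 51.8 ± 2.51 to 4.93 ± 0.651 CPM. Xist rose from 995 ± 14.0 to 1274 ± 39.3 CPM, while the Y-linked gene Kdm5d stood at 44.1 ± 0.430 and 45.7 ± 2.59 CPM, so that Xist and a Y-linked transcript were both detected in each group. Median log2 fold changes differed by gene type, at -0.04 for protein-coding genes, 0.15 for antisense genes, 0.13 for long intergenic RNAs and 0.20 for processed pseudogenes. By chromosome, the medians of genes with at least 5 CPM lay between -0.09 and 0.02.

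The first pattern is the extent of the difference beside a decrease of Phf8 transcript of 18.5%. How far the near identity of libraries within a group raises the number of calls stays open, since the 27.3% of changed genes that differed by at least 2-fold restates the pattern and 3305 and 811 genes changed with an assumed coefficient of variation of 0.2 and 0.4. A bias of GC content and gene length is argued against, because 94.9% of the genes with a 2-fold difference still differed by at least 2-fold after a smooth trend on both was removed. A difference between cultures or infections other than Phf8 may contribute and cannot be told apart from the effect of the shRNA, because infection and group are the same split. A loss of Phf8 protein larger than that of its transcript, and effects of the hairpin on other transcripts, were not tested.

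The second pattern is the increase of oligodendrocyte lineage genes. A smaller share of the main cell type would raise markers of every other type alike. The medians of the lists of other types ran from -1.23 for fibroblast and matrix genes to 0.67 for neuron markers. These lists cannot decide it, because they need not mark other cells in these cultures. In the control libraries, 3 of 7 tested microglial and 6 of 12 tested endothelial and mural markers had a mean of at least 1 CPM. In the fibroblast and matrix list, Fn1 stood at 418 CPM and Col1a1 at 0.310 CPM there. This explanation stays open. More cells of the lineage, or a shared programme, may also underlie the increase. In the second list, however, 44.4% of 27 tested genes rose (12, with 7 lower, median 0.05, camera adjusted p = 0.59). That share lies between the bounds set for and against more cells or a shared programme. These values leave open whether cells or expression per cell differed.

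The third pattern is the decrease of motile cilia genes. A trend on GC content and gene length is argued against, since their median was -1.89 after its removal. Fewer ciliated cells of an ependymal kind, or a lower shared ciliary programme, is a candidate explanation that stays open, since the 85.9% of tested members that fell is the pattern itself and does not bear on its cause. In the control libraries 49 of the 64 had a mean of at least 1 CPM. Bulk RNA cannot separate both versions, and a difference between cultures remains open here too.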
